A study of Rattus norvegicus with 6 samples.

How the data were processed

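RNA from 6 cultures of rat mesenchymal stromal cells was measured on Affymetrix RAE230A arrays, 3 from peripheral blood and 3 from bone marrow, with 1 blood and 1 marrow culture from each of 3 GFP transgenic rats. Per the labels' protocols, mononuclear cells of both sources were isolated on a density gradient, grown under the same conditions, passaged to passage 2, and 10 µg of total RNA per culture was labelled with biotin.

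The deposited values were taken to be on a log2 scale, because they run from 0 to 13.31 and natural logarithms of that size would mean signals far above the usual range of array scanners. The base is not stated in the sources used here, and the bacterial hybridisation controls, at 6.97, 7.77, 9.77 and 11.90 (bioB, bioC, bioD and cre), rise in uneven steps that do not settle it. Adjusted p do not depend on the base, while folds and 2-fold counts do. GCOS, the array maker's operating software, is the only tool named in the submitters' processing notes; the method that summarised probes into probe sets, the background correction and the normalization are not given in the sources used here. Array medians were 8.12 to 8.22, 86 of 95538 cells in 75 probe sets were empty and were left empty, and 94 cells were exactly 0. The 3' minus 5' signal of beta-actin was 0.24 to 0.38 and that of GAPDH 0.21 to 0.30 over the 6 arrays. Instrument setting files of the 6 arrays (per the file headers, chip type, fluidics station, module and scan) were read only for possible batches.

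Values were used as deposited, with a pseudocount of 0. The plan fixed before the data were examined said both that a table already on a log2 scale is used as it is and that arrays are scaled to a common trimmed mean where their 2% trimmed mean signals differ by 5% or more. They differed by 10.2%. These clauses can be read either way for this table. The first was followed, a choice made before any fit, and it gave more calls than the second: 175 against 109. The scaled values were run as an added alternative. No detection calls were used, so probe sets were kept where the signal was above the median of all values, 8.18 on the log2 scale, on at least 3 of 6 arrays in either group. This left 8135 probe sets after removing 57 control probe sets. A group whose level lies below that median has no known background, and its fold is approximate.

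Of 15923 probe sets, 12789 had 1 gene symbol in the platform annotation, 312 had several and 2822 had none. Of the former, 12754 had a gene identifier in the RefSeq gene table used here, and 0 symbols needed updating. Only probe sets with 1 symbol were given a gene name. Where a gene had several that passed the filter, the one of these with the highest mean log2 signal over all 6 arrays stood for the gene, which gave 6110 measured genes.

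Blood and marrow cultures were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the rat as a fixed term, because the series' design text states the pairing by animal, and Benjamini-Hochberg adjustment at an adjusted p of 0.05. Deviations of same-rat arrays from their group means correlated at -0.29, 0.30 and 0.33 for rats S4, S5 and S6. Those of blood and marrow arrays of different rats correlated at -0.47 to 0.42. The values thus do not show the pairing by themselves, and it was kept since the labels give it. Gene lists were tested with camera on the same fit, with a preset inter-gene correlation of 0.01, for 24 of 31 lists that had at least 5 measured genes, and counts within a list are given over all genes and adjusted over the list alone. No array pair was close to identical: the SD of the log2 difference was 0.264 or more in all 15 pairs. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

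Genes were named by a rule fixed before the data were examined: the 12 genes with the largest positive and the 12 with the largest negative log2 difference among those with adjusted p under 0.05 and the same sign in all 3 rats, to be filled by the smallest unadjusted p among genes with an absolute log2 difference of at least 1 where fewer passed (this was not needed); in each list up to 4 members with the smallest p; and always Ptprc, Cd34, Thy1, Cd44, Eng, Nt5e, Runx2, Sox9, Pparg, Alpl and Cxcl12 where measured. Cd34, Runx2 and Sox9 are named by no probe set in the annotation used here, and Ptprc and Pparg did not pass the filter on signal. Not every list member the rule allows is named in the text. Other kept probe sets of the genes named had the same sign, except 1 of Tpm1. Probe sets that the filter left out were fitted without a filter; of the genes past the threshold only Sfrp4 had one with the other sign, and Wt1 and Shox2 each had one of slightly higher mean signal and far smaller difference. The plan did not say whether the brightest probe set is chosen before or after the filter. Chosen before it, Wt1 and Shox2 would not have been tested.

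The fit was tested on simulated data: in 10 simulations of 8135 probe sets with the fitted variances, 200 of them changed, it found 66.1% of changes of 1 log2 unit, 96.4% of changes of 2 and 99.7% of changes of 3, and 5.31% of calls were false. A list of genes shifted by 0.3 was called in 10 of 10 simulations, and without a list change 0.1 lists were called on average. Simulated genes were independent, which real genes are not, and each change was set to the same size in all rats. The simulations therefore do not show how the list test behaves on these arrays. Nor do they show that the shares of found and false calls hold there.

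Alternatives fixed beforehand were pseudocounts of 1 and of the 40th percentile of all signals (211), no filter, a filter on all 6 arrays, quantile normalization, median centring, a fit without the rat block, the rat as a random block, an intensity trend with robust variances, array weights, leaving out each rat, other thresholds, an estimated correlation or fry for lists, and the mean of a gene's probe sets. The 20th percentile (103) as pseudocount and the trimmed mean scaling were added after the data were seen. A batch term could not be added: the fluidics station was the same for both arrays of a rat, so the rat term holds it, and all arrays were scanned on 1 day. Blood arrays ran in odd and marrow arrays in even fluidics modules, and in each rat the blood array was scanned before the marrow array. Module and scan order within a rat therefore cannot be told apart from group.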

Results

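Gene expression was measured in cultured mesenchymal stromal cells, the adherent fibroblast-like cells that grow out of the mononuclear fraction of blood or bone marrow, from 3 rats carrying a GFP transgene. From each rat, named S4, S5 and S6 in the labels, 1 culture was grown from peripheral blood and 1 from bone marrow under the same conditions, and total RNA of passage 2 cells was hybridised to 1 Affymetrix RAE230A array per culture. The 6 arrays make 2 groups of 3, blood cultures and marrow cultures, paired by rat. Each array carried 15923 probe sets, and array medians lay between 8.12 and 8.22 on the log2 scale. With 3 rats, the number of arrays limits the precision of every value below. Differences are blood minus marrow, in log2 units, with their SE; the base of the deposited logarithms was read from the values. Group levels are mean log2 signals ± SD (n = 3), and positions in the genome are not used here.

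The comparison asked how stromal cells grown from circulating blood differ from those grown from the marrow of the same animal. Among the genes past the threshold, Ptgis, Cdh2, Cadm1, Wt1 and Gata4 were higher and Aoc3, Hoxa10, Mmp13, Frzb and Aqp1 lower in blood cultures. Taking each gene's brightest probe set that passed the filter, the widest rise among named genes was that of Ptgis, the prostacyclin synthase. It had a log2 difference of 6.36 ± 0.63 and levels of 11.24 ± 0.92 in blood and 4.87 ± 0.88 in marrow cultures (adjusted p = 0.0114). Cdh2, which encodes N-cadherin, was higher by 5.58 ± 0.42 (adjusted p = 0.00484) and on a dimmer kept probe set by 6.94 ± 0.47 (adjusted p = 0.0036). Aoc3, an amine oxidase of the vascular wall, fell by 5.05 ± 0.69 (adjusted p = 0.0326).

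In all, 80 probe sets were higher and 95 lower in blood cultures among 8135 tested with limma, with the rat as a term of the fit and Benjamini-Hochberg adjustment, and 146 of these 175 changed at least 2-fold. All 175 changed the same way in all 3 rats, which is no test, because calling them on these same differences nearly ensures it. Of all tested probe sets 34.2% did so, where chance alone gives 25%. The higher probe sets stood for 57 genes and the lower ones for 78, and 26 had no single gene symbol, among them 15 higher and 11 lower. The largest difference of any probe set belonged to one of these, picked out after its values were seen, at 11.90 ± 0.52 in blood and 4.78 ± 0.49 in marrow cultures, a difference of 7.12 ± 0.33. Leaving out any rat leaves 1 residual degree of freedom. Without rat S4 no probe set, and so no gene named here, passed in limma, with 770 at an unadjusted p under 0.05 and a smallest adjusted p of 0.152, against 406 calls without rat S5 and 44 without rat S6. The differences of the 45 named genes past the threshold stayed without rat S4 at a median of 93.1% of their size (76.6% to 122%). These shares are no test, because the genes were chosen on all 3 rats and the remaining rats are part of the full mean. Bringing the arrays to a common trimmed mean, which one reading of the plan asked for, left 57 higher and 52 lower probe sets, all 109 of them among the 175, and 28 of the 45 genes named here as past the threshold.

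The 12 largest rises, ranked by each gene's brightest probe set among those that passed the filter, began with Ptgis and Cdh2. Cadm1, a cell adhesion molecule, was higher by 4.03 ± 0.32 (10.41 ± 0.85 against 6.38 ± 0.37, adjusted p = 0.00555), and the tetraspanin Tspan7 by 3.33 ± 0.24 (9.93 ± 0.76 against 6.60 ± 0.42, adjusted p = 0.0042). Timp3, an inhibitor of matrix metalloproteinases, rose by 4.14 ± 0.59 from 7.02 ± 0.63 in marrow cultures to 11.16 ± 1.41 (adjusted p = 0.0356). Bmp6, a bone morphogenetic protein, rose by 2.88 ± 0.15, or 7.36-fold, between levels of 7.90 ± 0.27 and 10.78 ± 0.29 (adjusted p = 0.00276). The kinase gene Plk2 rose by 2.64 ± 0.26, or 6.23-fold. The other genes among the 12 largest rises were LOC100910973 at 3.80 ± 0.60, Rpp25, a subunit of ribonuclease P, at 3.30 ± 0.19, and Nrep at 2.74 ± 0.17, together with Wt1 and Gata4 described below. Marrow levels of all 12 genes but Bmp6 and Plk2 were below the table's median of 8.18 on all 3 arrays, where no background level is known, so those folds are approximate.

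The 12 largest falls began with Aoc3 and Hoxa10. Mmp13, a collagenase, fell by 4.53 ± 0.31 from 11.92 ± 0.98 in marrow cultures to 7.39 ± 1.36 (adjusted p = 0.0036), and Mmp3, or stromelysin, fell by 3.87 ± 0.49 from 11.65 ± 1.51 to 7.78 ± 1.65 (adjusted p = 0.0245). Aqp1, a water channel, fell by 4.21 ± 0.23 from 11.38 ± 0.71 to 7.17 ± 0.15 (adjusted p = 0.00326), and its dimmer probe set differed by -6.38 ± 0.21. The imprinted noncoding RNA H19 differed by -3.38 ± 0.34, Tnn, which encodes tenascin-N, by -3.38 ± 0.41, and Cdo1, cysteine dioxygenase, by -3.36 ± 0.30. Rasd1, a Ras-related gene, differed by -3.75 ± 0.23, Gpr15lg by -3.61 ± 0.54 and Mlana by -3.49 ± 0.43. Hoxa10 and Frzb, described below, complete the 12 largest falls. Blood levels of Aoc3, Hoxa10, Frzb, Aqp1, Rasd1 and Mlana lay below the table's median on all 3 arrays, which leaves their folds approximate.

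**Figure D1:**
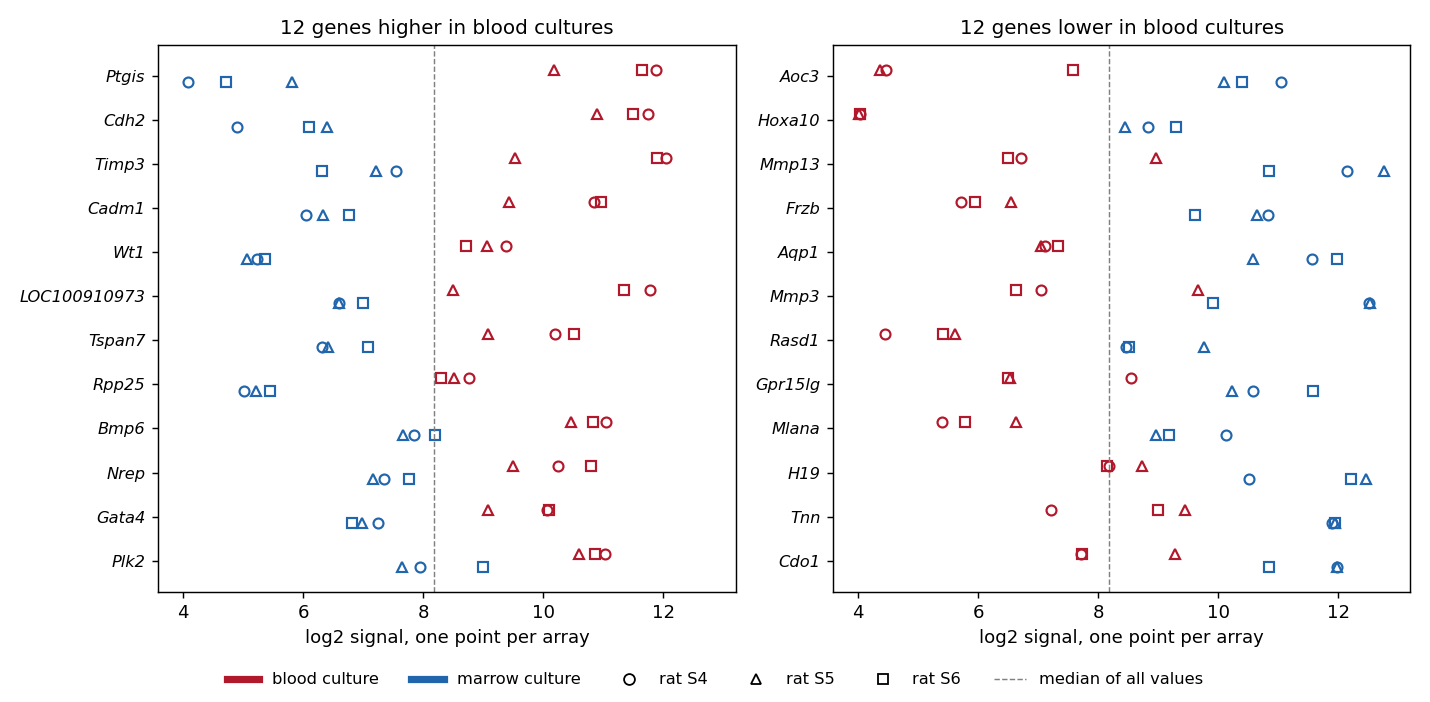
Log2 signal on each of the 6 arrays for the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in blood cultures, red for blood and blue for marrow cultures, with 1 symbol per rat and a dashed line at the median of all values, 8.18. In every gene shown the 3 blood arrays and the 3 marrow arrays do not overlap. This is no test, because the genes were chosen on these arrays for their large differences.

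Of the 13 measured genes in the list of homeobox and limb patterning genes, 1 rose, 3 fell and 9 did not pass, with the same counts when adjusted over the list alone. Hoxa10, a homeobox gene of the posterior trunk and limbs, stood at 8.86 ± 0.43 in marrow cultures and at 4.03 ± 0.01 in blood cultures, a difference of -4.83 ± 0.18 (adjusted p = 0.0017). Shox2, a limb homeobox gene, differed by -3.04 ± 0.25 (9.25 ± 0.34 in marrow, 6.22 ± 0.43 in blood) and Hoxd8 by -1.85 ± 0.28. Other probe sets of Shox2 lay below the filter and did not pass in the fit without a filter. Of these, 1 differed by only -0.20 ± 0.14 (adjusted p = 0.736) and 1 by -2.30 ± 0.34 (adjusted p = 0.112). In the other direction Gata4, a regulator of heart and visceral mesoderm, stood at 9.75 ± 0.58 in blood and 7.01 ± 0.21 in marrow cultures. It differed by 2.73 ± 0.23 (adjusted p = 0.00687), and by 0.96 ± 0.18 on a dimmer probe set (adjusted p = 0.167 without a filter). The counts use 1 probe set per gene, and only Gata4 was counted as risen. However, a kept probe set of Gata6, of the same list, was also higher in blood cultures in each rat. Picked after its values were seen, it stood at 9.84, 8.64 and 9.86 in blood and 7.73, 6.79 and 8.32 in marrow cultures. Wt1, a zinc-finger regulator of the mesothelium, epicardium and kidney, was at 9.05 ± 0.33 in blood and 5.22 ± 0.15 in marrow cultures, a difference of 3.83 ± 0.19 (adjusted p = 0.0026). A second probe set of Wt1, below the filter, differed by only 0.45 ± 0.13 and did not pass in the fit without a filter (adjusted p = 0.318). The mean signals of the 2 Wt1 probe sets over all 6 arrays were 7.14 and 7.15, so the large difference of Wt1 was seen on 1 of 2 probe sets of like brightness. In the list of epithelial and mesothelial genes only Wt1 and Msln, the mesothelial surface protein mesothelin, were bright enough to be tested, and Msln differed the other way, by -1.24 ± 0.11 (8.67 ± 0.43 in blood, 9.91 ± 0.42 in marrow, adjusted p = 0.00911).

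The Wnt antagonist genes Frzb, Sfrp1 and Sfrp4 fell in blood cultures. Sfrp2 and Dkk3, at -1.27 ± 0.63 and -0.18 ± 0.12, did not pass (adjusted p = 0.471 and 0.624). Of 13 measured Wnt and Notch pathway genes, 1 rose, 3 fell and 9 did not pass, and the counts were the same when adjusted over the list alone. The antagonist Frzb fell by 4.30 ± 0.28 from 10.37 ± 0.66 to 6.07 ± 0.43 (adjusted p = 0.00332). Its relatives Sfrp1 and Sfrp4 differed by -2.61 ± 0.28 and -2.17 ± 0.35 (adjusted p = 0.0141 and 0.0489). A dimmer probe set of Sfrp4, below the filter, differed by 0.15 ± 0.14 (adjusted p = 0.816 without a filter). The ligand gene Wnt4 rose by 1.47 ± 0.15 to 8.44 ± 0.17 (adjusted p = 0.0123). Of 24 TGF-beta and BMP pathway genes, 2 rose, none fell and 22 did not pass; adjusted over the list alone, 3 rose and 1 fell. The 2 were Bmp6 and Bambi, a membrane decoy receptor of the pathway, which differed by 2.24 ± 0.19 (8.66 ± 0.20 against 6.42 ± 0.26, adjusted p = 0.00693). The BMP antagonist Grem1 differed by -2.26 ± 0.43 and the activin subunit Inhbb by 1.19 ± 0.26, with adjusted p of 0.081 and 0.116. Among 18 growth factors only Mdk, midkine, passed, at -1.17 ± 0.14 (adjusted p = 0.0181); adjusted over the list alone, 6 fell and 1 rose. Fgf7, keratinocyte growth factor, differed by -4.73, -0.60 and -5.05 in rats S4, S5 and S6 and did not pass (adjusted p = 0.152).

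The 3 chains of collagen VI fell together: Col6a1 differed by -2.05 ± 0.24, Col6a2 by -1.84 ± 0.22 and Col6a3 by -1.87 ± 0.21, with levels of 10.66, 10.57 and 10.73 in marrow cultures and adjusted p of 0.0181, 0.0198 and 0.0162. They were the only ones of 21 measured collagens and fibre proteins past the threshold over all genes, and 18 did not pass; adjusted over the list alone, 7 fell and 1 rose. A dimmer probe set of Col6a2, below the filter, differed by only -0.84 ± 0.20 and did not pass in the limma fit without a filter (adjusted p = 0.252). Col14a1 differed by -2.97 ± 0.50 on its brightest probe set (adjusted p = 0.0542) and by -2.10 ± 0.30 on the other (adjusted p = 0.038). The fibrillar collagen gene Col1a1 was near the top of the scale in both groups, at 13.01 ± 0.02 and 12.54 ± 0.20, and differed by 0.47 ± 0.13 (adjusted p = 0.188). Of 15 basement membrane genes, 1 rose, 3 fell and 11 did not pass, against 2 and 3 when adjusted over the list alone. Col4a5, a collagen IV chain, was higher by 2.16 ± 0.13 (11.03 ± 0.29 against 8.87 ± 0.15, adjusted p = 0.00332), while Col18a1 differed by -2.61 ± 0.17, Col15a1 by -2.58 ± 0.38 and the laminin chain Lamb2 by -0.75 ± 0.12. Of 16 matrix proteases and inhibitors, 2 rose, 2 fell and 12 did not pass (3 and 5 when adjusted over the list alone), namely Timp3 and Mmp23, the latter at 1.40 ± 0.21, against Mmp13 and Mmp3.

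Of 13 measured surface markers used to define stromal cells, 1 rose, none fell and 12 did not pass; adjusted over the list alone, 2 rose and 2 fell. Eng, the TGF-beta co-receptor CD105, was higher by 1.62 ± 0.23, or 3.07-fold, at 10.50 ± 0.23 in blood and 8.89 ± 0.55 in marrow cultures (adjusted p = 0.038). Nt5e, or CD73, differed by 0.77 ± 0.15, Anpep, or CD13, by -1.31 ± 0.22 and Pdgfra by -1.93 ± 0.35, with adjusted p of 0.0862, 0.0574 and 0.0681. Cd44 was at 10.42 ± 0.18 and 10.41 ± 0.57, a difference of 0.01 ± 0.28. Thy1, or CD90, differed by -2.36, 1.74 and -2.43 in rats S4, S5 and S6, so its mean of -1.02 ± 0.83 did not stand apart from the spread between rats (adjusted p = 0.715). The chemokine gene Cxcl12, which holds blood stem cells in the marrow, was bright in both groups, at 11.84 ± 0.05 and 12.26 ± 0.34, and differed by -0.42 ± 0.17 (adjusted p = 0.358). Alpl, the bone alkaline phosphatase, differed by -0.06 ± 0.14 near the table's median, and Pparg and Ptprc lay under the level for testing, at 7.29 ± 0.10 and 7.55 ± 0.35 in blood and 7.63 ± 0.94 and 7.27 ± 0.58 in marrow cultures.

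Of 6 measured osteoblast genes, 9 adipocyte genes, 10 smooth muscle and pericyte genes and 3 cartilage genes, none passed over all genes. Adjusted over the list alone, 3 smooth muscle genes and 1 cartilage gene were higher and no osteoblast or adipocyte gene passed. These 3 were Tagln, an actin-binding protein gene, at 0.93 ± 0.21, Csrp1 at 0.81 ± 0.13 and Tpm1, a tropomyosin, at 0.66 ± 0.18, with adjusted p over all genes of 0.131, 0.0516 and 0.183. A further kept probe set of Tpm1 had the other sign, at -0.06 ± 0.15. Acta2, smooth muscle actin, differed by 0.61 ± 0.21 (adjusted p = 0.286). The cartilage proteoglycan gene Fmod differed by 1.53 ± 0.27 (adjusted p = 0.0647), Sparc by 0.48 ± 0.16, Spp1, osteopontin, by -1.06 ± 0.49 and Angptl4 by -1.54 ± 0.39. Among 8 insulin-like growth factor binding genes and partners, Igfbp7 rose by 1.28 ± 0.19 (adjusted p = 0.038), Stc1, a secreted glycoprotein of that list, fell by 2.14 ± 0.24 (adjusted p = 0.0162), and the counts were the same when adjusted over the list alone. Of 15 cholesterol synthesis genes only Lss, lanosterol synthase, passed, at -0.93 ± 0.12, and of 22 glycolysis and hypoxia genes only Egln3, a prolyl hydroxylase, passed, at 1.59 ± 0.13. Both counts were the same when adjusted over the list alone. None of 16 chemokines and cytokines passed over all genes, while 2 were higher and 1 lower when adjusted over the list alone, namely Ccl20 at 1.53 ± 0.30, Il33 at 1.11 ± 0.25 and Cxcl3 at -0.73 ± 0.16.

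Of the pan-leukocyte genes on the array 6 of 12 passed the filter on signal, and of the macrophage and monocyte genes 11 of 15. Those below it included Ptprc, Coro1a, Csf1r and Itgam. None of those 6 and 11 passed in limma, over all genes or adjusted over the list alone, and their median differences were 0.37 and 0.33. Some were bright in both kinds of culture. Cd68, a macrophage lysosomal protein, stood at 10.98 ± 0.03 in blood and 10.51 ± 0.77 in marrow cultures, Tyrobp, a myeloid adaptor, at 10.64 ± 0.19 and 10.24 ± 0.43, and Cd53 at 10.09 ± 0.14 and 9.52 ± 0.64. The differences of these genes lay mostly in rat S4, with 1.36 for Cd68, 0.97 for Tyrobp, 1.47 for Cd53, 1.38 for Laptm5 and 1.31 for Ctss, against 0.57 or less in rats S5 and S6. Pf4, a platelet chemokine also made by macrophages, was at 11.74 ± 0.17 and 11.25 ± 0.48. Lists of other cell types were mostly too dim to test: 2 of 12 lymphocyte genes on the array, 1 of 8 granulocyte and mast cell genes, 4 of 7 erythroid and platelet genes, 2 of 15 endothelial genes and 2 of 17 skeletal and cardiac muscle genes passed the filter on signal, and none of those tested passed the threshold, over all genes or adjusted over the list alone. The same held for 6 neural and glial genes, where Ncam1 differed by 1.34 ± 0.38 (adjusted p = 0.199).

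As a set, only the unfolded protein and stress response genes stood apart from the other genes. Their 24 measured members had a median difference of 0.24 with 16 above 0, and camera with a preset correlation gave an adjusted p of 0.0145 over 24 lists. With an estimated correlation the adjusted p was 0.767, and without rat S4 it was 0.0986. No member passed over all genes or when adjusted over the list alone. The members with the smallest p were Ddit3, the stress-induced factor CHOP, at 1.30 ± 0.31, Trib3 at 0.92 ± 0.20, the chaperone gene Hsph1 at 0.70 ± 0.18 and the cell cycle inhibitor gene Cdkn1a at 0.57 ± 0.18. Each of the other 9 ways of parting the 6 arrays into 3 and 3 called 2 to 8 lists by the same test, although those splits still carry part of the difference between blood and marrow. The 2 next lists by camera were the pan-leukocyte and the smooth muscle genes, each with an adjusted p of 0.0532, or 0.767 with an estimated correlation. No single gene passed over all genes among 9 cell division genes, 5 MHC class II and antigen presentation genes, 6 interferon response genes, 19 immediate early genes and 38 ribosomal proteins; adjusted over the list alone, 1 interferon response gene, Ifitm3, passed at -0.53 ± 0.13. Mcm2, a replication licensing factor, differed by -0.51 ± 0.16, B2m by 0.26 ± 0.15 and Myc by 0.61 ± 0.18. Median, mean and direction of the set test differed in sign for osteoblast genes (0.11, -0.03 and upward), basement membrane genes (0.14, -0.05 and upward), homeobox and limb patterning genes (0.02, -0.39 and downward) and immediate early genes (-0.04, 0.03 and upward).

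**Figure D2:**
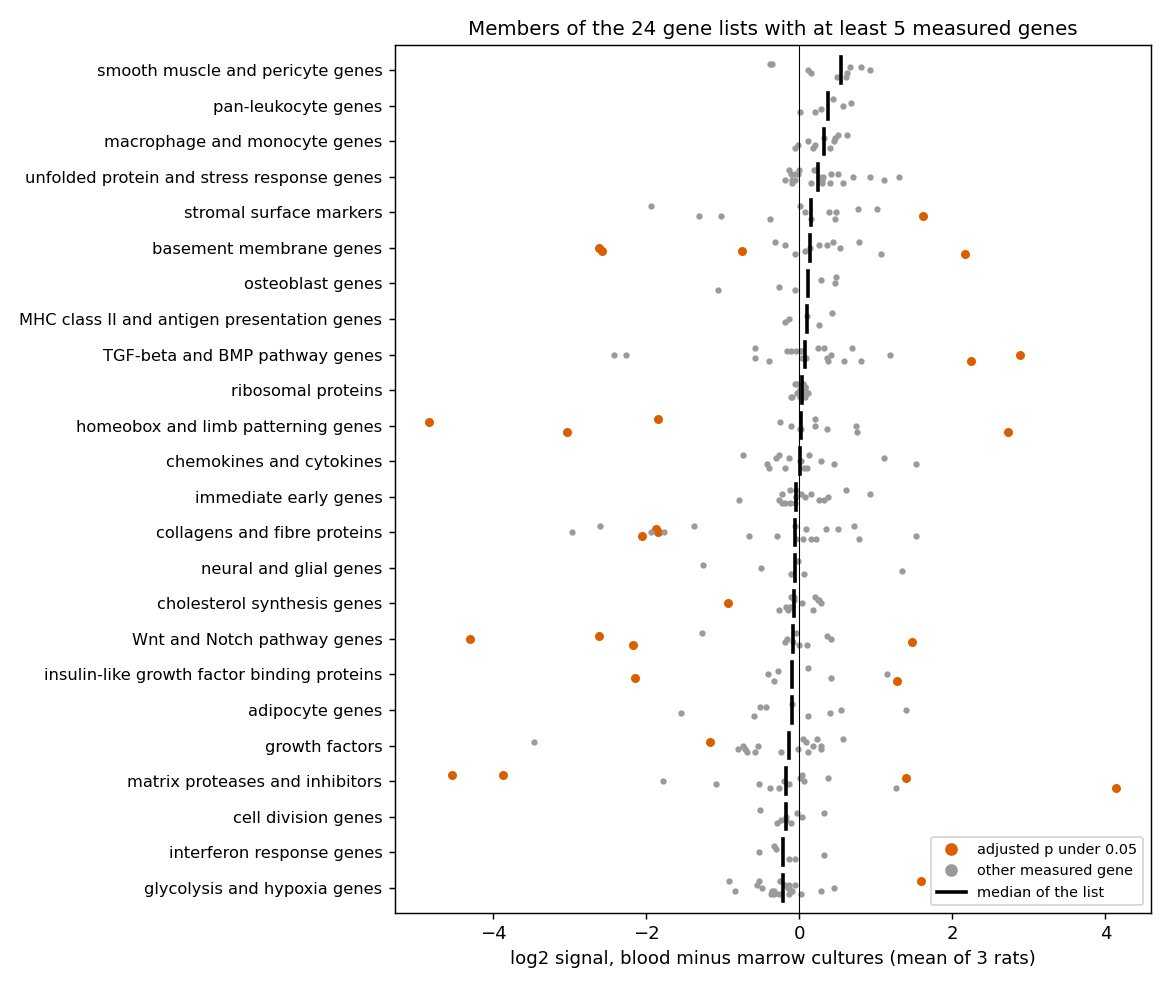
Log2 difference between blood and marrow cultures, averaged over 3 rats, for each measured member of the 24 gene lists with at least 5 measured genes, with members past an adjusted p of 0.05 in orange and a black bar at each list's median. List medians lie between -0.21 and 0.55, while single members reach -4.83 and 4.14.

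Between arrays, log2 signals of the tested probe sets correlated at 0.889 to 0.972 within a group and at 0.816 to 0.893 between groups, across probe sets, which are not independent replicates. The blood cultures of rats S4 and S6 were the closest pair of arrays, at 0.972. The blood culture of rat S5 correlated at 0.907 and 0.889 with the other blood cultures and at 0.893, 0.888 and 0.863 with the marrow cultures of rats S4, S5 and S6. Its differences from its marrow partner were smaller: 329 tested probe sets differed at least 2-fold in rat S5, against 547 in rat S4 and 423 in rat S6.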

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

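Calls depended on how the arrays were scaled and filtered and on single rats. The trimmed mean scaling and the 20th percentile pseudocount were chosen after the data were seen. Of 85 named genes, 45 passed the threshold, and of 684 further values of these under all alternatives 495 kept their side of the threshold and 189 did not. Their signs are no test when a rat is left out, because all had the same sign in all 3 rats. Their sizes are no test there either, because the remaining rats are part of the mean on which the genes were chosen. Leaving out 1 rat gave 0 to 197 higher probe sets, 0 to 209 lower, 0 to 344 changed at least 2-fold and 0 to 7 lists, with all lowest counts without rat S4, the most lists without rat S6 and the other highest counts without rat S5; without rat S4 limma found 770 probe sets at an unadjusted p under 0.05, and the 45 genes kept 76.6% to 122% of their difference. Fewer animals leave 1 residual degree of freedom there. Without rat S6, 13 of the 45 passed, and without rat S5, 44. Without the replicate block, 55 probe sets were higher, 75 lower and 104 changed at least 2-fold, with 3 lists past the threshold, and 33 of the 45 genes passed; with the rat as a random block 2 lists passed. No filter gave 42 higher, 40 lower, 82 changed 2-fold and 4 lists over 15866 probe sets, with 22 of the 45 genes past the threshold; requiring all 6 arrays gave 63 lower, 66 changed 2-fold and 5 lists, since it drops genes dim in 1 group, and only 9 of the 45 genes were measured, all past the threshold. Quantile normalization gave 51 lower and 95 changed 2-fold, median centring 47 and 90, and trimmed mean scaling 52 and 96, with 27, 27 and 28 of the 45 genes; the cause was not tested. At an adjusted p of 0.10 there were 133 probe sets higher in blood cultures and 161 probe sets lower in blood cultures, and at an unadjusted p under 0.05 with a 2-fold change 147 and 151, or 298 probe sets changed at least 2-fold. Lists past the threshold numbered 4 with the 40th percentile pseudocount, 2 with the 20th percentile, 4 with intensity trend and robust variances, 2 with array weights, 6 with the mean of probe sets and 0 both with an estimated correlation and with fry for a shift in 1 direction. The p of fry for changes in either direction, which was not among the alternatives and does not compare a list with other genes, passed for 10 lists, without the stress list (adjusted p = 0.303). The unfolded protein and stress response list had adjusted p from 0.00106 to 0.767 over these. Cd44 and Alpl, which did not pass, lost or changed their sign: Cd44 with the 40th percentile pseudocount (0.00), with array weights (-0.25) and when 1 rat was left out (-0.32 to 0.41), Alpl with array weights (0.00) and when 1 rat was left out (-0.14 to 0.07). The excess of within-group over between-group correlation, 0.076, was 0.023 with no filter, where probe sets near background enter. Without detection calls, signal over background is unknown for probe sets below the median. A batch term was not run. The station was the same for both arrays of a rat, so the rat term holds it. Module and scan order within a rat coincided with group.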

Other observations

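The limma fit and the camera tests without a filter were among the alternatives fixed beforehand, but the genes and lists shown from them were picked afterwards. Except for these, the muscle gene list written before its values were seen and the counts of other splits, all tests in this part were chosen after the results were seen. Several genes too dim for the filter also separated the groups in the limma fit without a filter, picked here for passing it. Hoxa11, a limb homeobox gene, stood at 7.08, 6.58 and 7.87 in the marrow cultures and at 4.20, 4.40 and 5.08 in the blood cultures of rats S4, S5 and S6 (-2.62 ± 0.19, adjusted p = 0.023), beside its neighbour in the cluster, Hoxa10. Pgr, the progesterone receptor, differed by -1.67 ± 0.12 (adjusted p = 0.023), Crabp2, a retinoic acid binding protein, by -2.85 ± 0.30 (adjusted p = 0.0478) and Map2, a microtubule protein of neurons, by -3.39 ± 0.34 (adjusted p = 0.0429). Gpc3, a proteoglycan of growing tissues, differed the other way, by 3.57 ± 0.34 (adjusted p = 0.0385), as did Tmtc1 by 2.68 ± 0.23 (adjusted p = 0.0334). Cx3cl1, the chemokine fractalkine, was at 8.58, 10.15 and 8.15 in marrow and near 6.10, 6.05 and 6.03 in blood cultures, and did not pass (adjusted p = 0.0954). Most of these levels lie below the table's median, so the sizes are approximate.

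The differences of rat S5 had a slope of 0.58 on the mean of the other 2 rats, over the 300 probe sets largest there. Slopes taken likewise for rats S4 and S6 were 1.10 and 0.84. Each slope used its own probe sets, and the means for rats S4 and S6 hold the smaller differences of rat S5. Choosing the largest in the other rats also lowers each slope, so the slopes are only roughly comparable. For both technical explanations a first test came out otherwise and was replaced by another after its result was seen. Of 25 probe sets bright in marrow and dim in the other blood cultures, 5 needed under 2% and 14 over 10% of marrow RNA. This did not decide. The mean step from 3 bioB to 2 cre control probe sets was 3.68 on the array of rat S5's blood culture, against 3.75 to 4.0 elsewhere. These are other control probe sets than the ones whose levels are given with the processing. The step was smaller on that array, as a compressed scale needs, but by far less than the slope, taken at face value, would need. Marrow-like cells in that culture need 1 share of marrow RNA for all genes, but these 25 needed a median of 11.4% (quartiles 2.35% and 49.7%) and 35 with the opposite pattern 57.3% (quartiles 38.1% and 75.5%), which argues against a mixture as the whole cause. The SD of log2 values, 1.10 against 1.09 to 1.11 on the others, argues against a compressed scale. A difference between the animals may be the source and was not tested, with 1 blood culture per rat.

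Higher Wt1, Gata4 and Cdh2 with lower Hoxa10 and Shox2 in blood cultures raised the hypothesis that these cultures hold cells of a visceral or cardiac lining. For Wt1 it rests on 1 of 2 probe sets, as the second, below the filter, differed by only 0.45 ± 0.13 (adjusted p = 0.318 without a filter). Of the 2 other Shox2 probe sets, also below the filter, 1 differed by -2.30 ± 0.34, near the value of the tested one, and 1 by only -0.20 ± 0.14 (adjusted p = 0.112 and 0.736). Wt1 aside, 7 listed mesothelial genes on the array (5 also in the fixed lists) had a median difference of 0.09 (quartiles -0.13 and 0.14). Msln was lower by the test in the results. These genes did not rise as a set, but this does not decide on mesothelial cells. Only 1 of the 7 had a mean level above the table's median in blood cultures. Keratins Krt8, Krt18 and Krt19 were at 7.31, 6.13 and 6.33 in blood cultures, below that median, where no background level is known. Their flat values cannot show the cells absent. The 1 member higher by 1 or more was Gpm6a, at 7.93, 6.61 and 8.61 in blood and 6.28, 6.02 and 6.38 in marrow cultures, a difference of 1.49 (adjusted p = 0.214). Heart muscle genes did not rise as a set either, with a median of -0.02 over 15 genes (quartiles -0.21 and 0.08) and none higher by 1 or more. Mean levels of only 2 of the 15 in blood and 3 in marrow cultures lay above the table's median, so heart muscle cells are not decided on. Myh6 was bright in both groups, at 10.67, 10.73 and 10.67 in blood and 10.60, 10.76 and 10.72 in marrow cultures. Whether its probe set reports that gene was not tested. Stromal cells of a body region with another HOX pattern remain a candidate explanation, which the design does not test. Fluidics module and scan order within a rat cannot be told apart from group.

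Muscle genes were lower in blood cultures among dim probe sets: without a filter, camera gave the 17 skeletal and cardiac muscle genes an adjusted p of 6.44e-05 with a median of -0.34, or 0.946 with an estimated correlation, and none of the 17 passed singly. Myod1, the myogenic regulator, was at 5.81, 9.09 and 10.17 in the marrow cultures of rats S4, S5 and S6 and at 4.56 or less in blood cultures (adjusted p = 0.25), and Acta1, skeletal actin, at 7.12, 9.10 and 8.09 against 5.15, 5.20 and 5.15 (adjusted p = 0.0743). All 7731 dim probe sets had a median difference of 0 (quartiles -0.15 and 0.15), so dim probe sets as a whole did not shift with the muscle genes. The background correction and normalization of the deposited values are unknown and may have set this median. It therefore does not decide on a background difference at particular dim probe sets. A second list of muscle precursor and fibre genes was written before its values were seen, with a median under -0.25 set as the bound. Its 26 genes on the array had a median of -0.26, but 2 of them, Des and Tpm2, were also in the fixed lists and were first counted in error. The 24 others had a median of -0.21 (quartiles -0.59 and -0.04) and so missed the bound, with Klhl41 at -3.23 (adjusted p = 0.0254). That median was lower than all but 0.13% of 10000 random lists matched on level. Members of the random lists were drawn independently, so this share leaves out correlation between genes and the spread between rats. Mb and Ckm differed by 0.21 and -0.02. Muscle precursor cells carried over with the marrow cultures may be a source, and so may stromal cells that themselves transcribe these genes; the values leave this open.

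Without a filter the 30 cell division genes had a median difference of -0.26 and an adjusted p of 6.44e-05 by camera, or 0.946 with an estimated correlation. The 30 TGF-beta and BMP pathway genes and the 24 unfolded protein and stress response genes passed upward by camera (adjusted p = 0.0128 and 0.00708). With an estimated correlation both were at 0.946.

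The 6 arrays can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. With the rat term, the real split called 175 probe sets, 146 of them changed at least 2-fold, and was the 1 split of 10 with counts as large; the highest of the others was 0 for both. Of the 10, 4 part all 3 rats, and the other 3 of these, which exchange blood and marrow within 1 rat, gave 0. For gene lists all 10 splits called at least as many as the real 1, with 8 as the highest of the others. Every other split still carries part of the difference between blood and marrow. With the rat term that part enters the residual, so few or no probe set calls could come from the other splits. Neither the probe set counts nor the list counts therefore separate the groups from other structure of the arrays.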
